A study of Macaca mulatta with 11 samples.

How the data were processed

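DNA methylation was measured in prefrontal cortex area 46 of 11 rhesus macaques (Macaca mulatta), 2 from cohort 10 and 9 from cohort 14. Per the labels, the tissue was collected before the animals had drunk alcohol, and each animal's label carries its cohort, its age and an ethanol value for 6 months. That value is called the intake value here. The labels used here state no unit for age or for intake. Per the labels' protocols, DNA was extracted with the Qiagen AllPrep kit and libraries were made with the SureSelect XT Human Methyl-Seq kit, which enriches bisulfite libraries with probes designed on the human genome. The measured positions are therefore those where macaque DNA was caught by human probes. FastQC and Bismark were used, per the submitters' processing notes. Their versions and the genome build are not given in the sources used here.

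The authors deposited 1 table of methylated read counts and 1 table of total read counts per CpG position and library, both as whole numbers that were not normalized. Each table held 11 columns whose names matched a library of the samples and 5 further columns that matched none. The 5 further columns were not used. The tables listed 3115109 positions on chromosomes 1 to 20. Tested on the values, the lowest methylated count and the lowest unmethylated count at any position were both 1, and the lowest total was 12. A table of raw calls would hold counts of 0, so the counts look as if 1 had been added to both. No label or header states such a step, and the counts were tested as deposited. An alternative took 1 from each methylated count and 2 from each total. Total counts ran from 479979855 to 934657900 per library, with a mean of 154.1 to 300.04 reads per position. PCR copies cannot be told from independent molecules in these counts, so a depth in reads overstates the number of molecules behind a level.

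Every position passed the coverage minimum of 10 in all animals. Positions at most 200 bp apart were joined to regions, which were split at 1000 bp and kept with at least 5 CpGs. Of 140730 regions, 119749 with a pooled methylation level from 5% to 95% were tested, and 17549 below and 3432 above these limits were left out. The tested regions had a median of 10 CpGs, a median length of 326 bp and a median of 1944 reads per region and animal. Single CpGs with a pooled level from 5% to 95% were tested as well, 1874277 in all. At 63630 places 2 positions 1 bp apart were both listed, as the strands of a single CpG would be, and each was counted as a position.

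Methylated and unmethylated counts of a region or CpG were fitted by logistic regression on the intake value with cohort as a covariate. The model was quasi-binomial, its dispersion was shrunk across regions by the empirical Bayes method of limma, and the two-sided p-values were adjusted by the Benjamini-Hochberg method at 0.05. Slopes in percentage points per unit of intake and their standard errors came from least squares on the levels with the same design. The fit was checked against the generalised linear model of R and tested on simulated data. In a simulation without change, 0 of 119749 regions were called and 4.57% had an unadjusted p under 0.05. In a second simulation of the comparison with intake over 119749 regions, 200 regions were changed, 50 at each of 4 slopes. At logit slopes of 0.25, 0.5, 1 and 1.5 per unit of intake, 0%, 18%, 62% and 86% of the 50 were called, and 2 unchanged regions were called. Both simulations drew each region independently, with no effect shared by the regions of an animal and no cohort difference. In the real data, random reassignments of intake gave 2992 to 17569 regions at an unadjusted p under 0.05. The simulated rates therefore need not hold for these data. The alternatives were limma on logit methylation and the edgeR test for bisulfite counts. Work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3, limma 3.58.1 and edgeR 4.0.16.

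The mean level over all positions was related to intake by Pearson's r and Spearman's rho with two-sided permutation p-values, from 100000 resamples for 11 animals and by full enumeration for fewer than 10. Regions, settings, tests and alternatives were fixed before the data were examined. The rule for the regions named here was fixed then too. With fewer than 10 regions past the threshold, it took the 10 smallest p-values in each direction among regions whose slope kept its sign in cohort 14 alone and in every fit without 1 animal, described as not having passed. The part of the rule that asked for a nearby gene could not be applied. Levels are also given for the 6 animals with an intake value below 3 and the 5 at or above 3, for description only.

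Planned tests of promoters, of gene classes and of gene lists were not run, because they need gene positions on the build of the files. The gene table used here is of another assembly (T2T-MMU8v2.0). Of its 41046 gene ends, 4.45% had at least 10 measured positions within 500 bp, against 4.35% to 3.66% after shifting the genes by up to 2000000 bp, so its coordinates were not used and no gene name is given. Coordinates are those of the files. In place of gene classes, positions were grouped by the number of measured CpG positions within 250 bp on either side, a choice made after seeing the data. The alternatives tried were other covariates, cohort 14 alone, a coverage minimum of 20, ranks and classes of intake, other region limits, positions like C to T variants or of extreme coverage left out, and each animal left out. Added after seeing the data were the removal of the added counts, a term or correction for the mean level at positions under 5% pooled methylation, and fits without the 4 libraries with over 6% of positions at the lowest unmethylated count.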

Results

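Capture bisulfite sequencing counted methylated and unmethylated reads at 3115109 CpG positions in the prefrontal cortex of 11 macaques that had not yet drunk alcohol. Area 46 lies in the dorsolateral prefrontal cortex, a region involved in working memory and the control of behaviour. The comparison asked whether methylation before drinking was related to the ethanol value later recorded for each animal over 6 months. Intake values ran from 1.69 to 4.31, with 2.11 and 3.19 in the 2 animals of cohort 10. Ages ran from 5.02 to 5.44, and age and intake had a Pearson correlation of 0.222. Libraries held 479979855 to 934657900 counts in all.

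Methylation followed local CpG density. The mean pooled level was 76.1% at positions with 1 to 4 measured CpGs within 250 bp, 70.2% with 5 to 9, and 56.7% with 10 to 19. It was 25.6% with 20 to 39 and 13.4% with 40 or more. Over all positions, 44.3% lay under 20% methylation, 24.3% between 20% and 80%, and 31.4% over 80%. The 11 animals were alike in most regions: the median range between the lowest and the highest animal was 10.1 percentage points over 140730 regions, and 324 regions had a range above 50 points. At 54189 positions, 1.74% of all, at least 1 animal lay under 20% and another over 80%.

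No region passed the threshold for a relation to intake. The region nearest to it lay on chromosome 19 from 55104721 to 55105139 and held 29 CpGs. Its level fitted a slope of -8.79 ± 1.196 percentage points per unit of intake (SE, n = 11), with an adjusted p of 0.169 in the moderated logistic model. It was 24.1% ± 7.45 (SD, n = 6) in the animals with an intake value below 3 and 13.9% ± 3.37 (SD, n = 5) in the others, and the classes overlapped. A region of 32 CpGs on chromosome 1 from 221230127 to 221230608 came next. Its levels were 91.1% ± 1.74 (SD, n = 6) and 86.1% ± 1.72 (SD, n = 5), its slope was -3.78 ± 0.58 points per unit, and its adjusted p was 0.882.

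Among slopes above 0, the smallest p belonged to 54 CpGs on chromosome 15 from 1649149 to 1649790. The level there was 86.7% ± 1.99 (SD, n = 6) below an intake value of 3 and 90.4% ± 1.39 (SD, n = 5) at or above it. A region of 41 CpGs on chromosome 14 from 18510533 to 18511519 had 11.5% ± 1.23 and 16.2% ± 3.24 in the same classes. A region of 14 CpGs on chromosome 19 from 47457379 to 47457614 had 18.3% ± 2.95 and 25.3% ± 2.34, with the steepest slope of the 10 named, 5.52 ± 0.81 points per unit. Over the 10 regions named for a positive slope, slopes ran from 1.68 to 5.52 points per unit, CpGs from 13 to 92, and the adjusted p rounded to 1 for each. Over the 10 named for a negative slope, slopes ran from -9.20 to -2.07 points per unit and CpGs from 5 to 79. The steepest of these lay on chromosome 1 from 177567669 to 177568079, where 11 CpGs had 58.7% ± 3.39 (SD, n = 6) and 45.9% ± 4.03 (SD, n = 5). The classes of animals did not overlap in 3 of the 10 regions with a positive slope and in 2 of the 10 with a negative slope. Regions were chosen for small p-values, so these levels overstate what other animals would show. Each region had at least 1086 reads in every animal. In each direction, 3 of the 10 regions held at least 1 position with an animal under 20% and another over 80%, as a sequence variant would give.

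**Figure D1:**
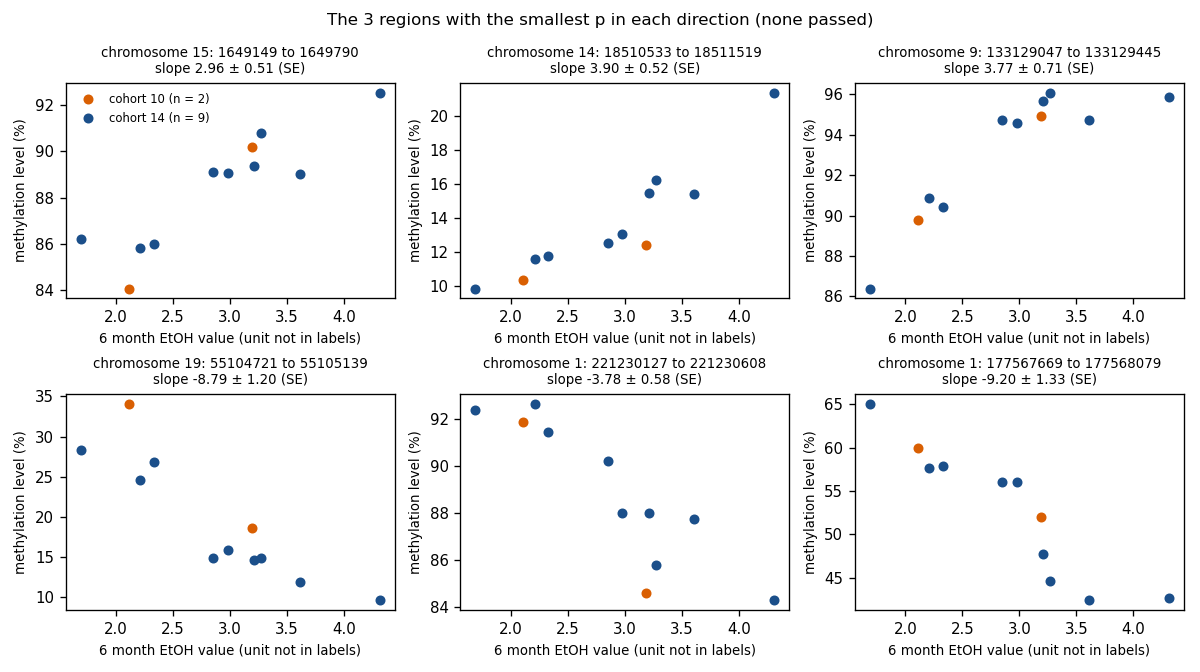
Methylation level (%) of each animal against its intake value, whose unit the labels do not state, in the 3 regions with the smallest p-values for a positive slope (top) and for a negative slope (bottom). Points are single animals, with cohort 10 in orange (n = 2) and cohort 14 in blue (n = 9), and none of the 6 regions passed the threshold.

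Of 119749 regions, 0 had an adjusted p under 0.05 in the moderated logistic model, and 3502 (2.92%) had an unadjusted p under 0.05. That number was 6418 (5.36%) without animal 9 of cohort 14 and 9084 (7.59%) with mean methylation as a covariate, and 0 regions passed in either. Limma on logit methylation called 0 regions with 4045 at an unadjusted p under 0.05, and edgeR called 0 with 3852. Of 1874277 single CpGs, 0 passed, 55443 had an unadjusted p under 0.05, and limma called 0 with 64881. With intake as 2 classes in place of a number, 8 CpGs passed, 2 higher and 6 lower in the animals at or above 3. The median standard error of a region's slope was 1.53 points per unit of intake. The 95% interval of the slope lay within 5 points per unit on either side of 0 in 54.0% of regions and within 10 points in 89.5%. Precision depended on the level: the interval lay within 5 points in 89.6% of regions pooled at 5% to 20%, and in 26.0% of those between 20% and 80%.

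The direction of slopes was also counted by CpG density, a split chosen after seeing the data. In the 25% of regions with most CpGs per bp, 58.1% of slopes were above 0. The share lay between 42.3% and 57.4% over 99 random reassignments of the intake values among animals, so 1 of the 100 arrangements, the real one, lay as far from 50%. Over all tested regions the share was 53.9%, a distance from 50% that 39 of the 100 reached. In the 25% with fewest CpGs per bp it was 50.9%, a distance that 89 of the 100 reached. The difference between the densest and the sparsest 25% was 7.17 points. Of the 100 arrangements, 4, the real one included, gave a difference as large in either direction. By pooled level, 64.5% of least-squares slopes were above 0 in regions at 5% to 20%, 52.9% at 20% to 80% and 52.6% at 80% to 95%. No reassignments were drawn for these shares. Incomplete bisulfite conversion alone would give larger slopes at low levels. At positions with 20 or more CpGs within 250 bp it would give 0.1457 points per unit at 5% to 20% and 0.0168 at 80% to 95%. Whether conversion accounts for these shares, or for that of the densest regions, was not tested.

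**Figure D2:**
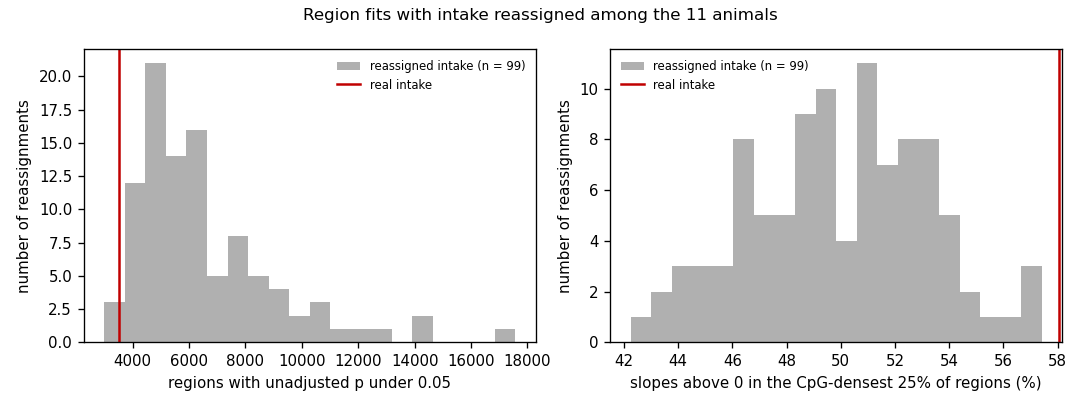
Number of regions with an unadjusted p under 0.05 (left) and share of slopes above 0 (%) in the 25% of regions with most CpGs per bp (right), in 99 random reassignments of intake among the 11 animals (grey bars) and for the real values (red line). The real values gave 3502 regions, against a median of 5744, and a share of 58.1%, above the highest other share of 57.4%; without animal 9 of cohort 14, for which no reassignments were drawn, there were 6418 regions.

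Levels were also averaged over whole classes of positions. The mean level over all positions ran from 43.7% to 44.5% and had a Pearson r of 0.57 with intake (permutation p = 0.0677, adjusted 0.135) and a Spearman rho of 0.464 (permutation p = 0.157, adjusted 0.313). At positions with 20 to 39 CpGs within 250 bp, the level ran from 25.3% to 26.1%, with a slope of 0.222 ± 0.0738 points per unit (SE, n = 11). There r was 0.703 (permutation p = 0.0161, adjusted 0.0965) and rho 0.673 (permutation p = 0.0273, adjusted 0.155). With 40 or more CpGs, r was 0.625 (permutation p = 0.0395, adjusted 0.118) and rho 0.609 (permutation p = 0.0517, adjusted 0.155). With 1 to 4 CpGs, r was 0.0825 (permutation p = 0.81, adjusted 0.81) and rho 0.0545 (permutation p = 0.881, adjusted 0.881). These were 6 relations, the overall mean and 5 density classes, and none passed after adjustment.

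Without the 2 animals farthest from the median intake, r was 0.328 for all positions (exact permutation p = 0.387) and 0.613 for 20 to 39 CpGs (exact permutation p = 0.0794). Without the animal of lowest intake alone, animal 4 of cohort 14, r for 20 to 39 CpGs was 0.621 (permutation p = 0.0543), and without the animal of highest intake alone, animal 9, it was 0.698 (permutation p = 0.0266). Within cohort 14 alone, r was 0.489 for all positions (exact permutation p = 0.181) and 0.695 for 20 to 39 CpGs (exact permutation p = 0.0371). Cohort 10, with 2 animals, gives no correlation of its own. The order of the density classes depended on 4 libraries of cohort 14, animals 3, 6, 7 and 8, which had the largest shares of positions at the lowest unmethylated count. Without them, a choice made after seeing the data, r over 7 animals was 0.612 for 1 to 4 CpGs (exact permutation p = 0.15), 0.727 for 5 to 9 (exact permutation p = 0.098), 0.882 for 10 to 19 (exact permutation p = 0.00913), 0.941 for 20 to 39 (exact permutation p = 0.00278) and 0.704 for 40 or more (exact permutation p = 0.0833). For all positions it was 0.909 (exact permutation p = 0.00615).

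**Figure D3:**
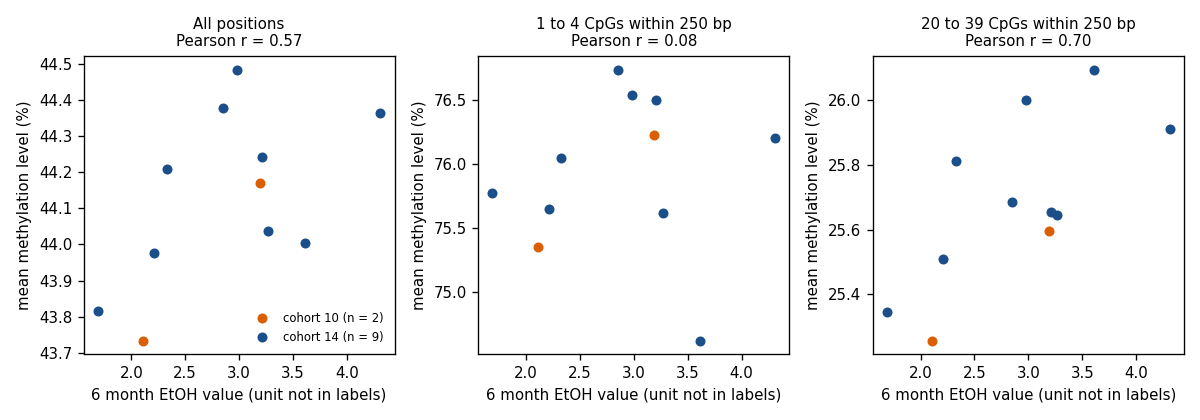
Mean methylation level (%) of each animal against its intake value, whose unit the labels do not state, over all positions, positions with 1 to 4 CpGs within 250 bp and positions with 20 to 39. Points are single animals, with cohort 10 in orange and cohort 14 in blue, and Pearson's r over 11 animals was 0.57, 0.0825 and 0.703.

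Cohorts 10 and 14 did not differ in any region at the threshold. In the same moderated logistic model, 0 of 119749 regions passed for cohort, 2956 had an unadjusted p under 0.05, and the smallest adjusted p was 0.645. Cohort 10 had 2 animals, both younger than every animal of cohort 14, so cohort and age cannot be told apart here. With 1 of the 2 animals left out, the comparison rested on the other, and the calls were regions in which that animal alone was higher. Without animal 1 of cohort 10, 1 region passed, 26 CpGs on chromosome 16 from 4972464 to 4972831, at 54.2% in animal 2 against 1.91% in animal 1 and 4.04% ± 3.34 (SD, n = 9) in cohort 14. Without animal 2, 2 regions passed. These were 81 CpGs on chromosome 6 from 69778700 to 69779693, at 20.2% in animal 1, and 35 CpGs on chromosome 13 from 97174588 to 97174999, at 71.8% in animal 1 against 11.5% ± 2.64 (SD, n = 9) in cohort 14. These 3 regions are named after their values were seen.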

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

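Of the tests given here, the one on positions higher in 1 animal was chosen after its result was seen. In 31 sets of values over the 9 animals of cohort 14, 2 held an animal far from the others. Chance gives about 1 in 20 for unselected, normally spread values. The sets include the 20 named regions, chosen for small p-values against intake, so that rate need not hold here. The region of 6 CpGs on chromosome 16 from 47376429 to 47376863, 1 of the 10 named for a negative slope on intake, had a level of 87.7% in animal 9 of cohort 14 and 94.6% to 97.4% in the others of that cohort. Animal 2 of cohort 10, with an intake value of 3.19, was lower still at 84.7%. Animal 9 has the highest intake value, 4.31, and without it the region's logit slope went from -0.80 to -0.62 per unit of intake. Animal 6 of cohort 14 held 45 regions under 55% in which every other animal lay over 70%, against 3 to 14 such regions in the other animals of cohort 14.

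Animal 6 was 1 of 4 libraries, with animals 3, 7 and 8 of cohort 14, in which 6.32% to 7.19% of positions had the lowest unmethylated count, against at most 4.70% in the other 7. Near 50% methylation their levels scattered as 13.1 to 22.8 independent reads would, against 24.98 to 38.55 in the other 7. Median depths were 223 to 320 reads in the 4 and 196 to 389 in the other 7, so all libraries scattered more than their depth would give. Sequence variants read as unmethylated could explain positions lower in 1 of these animals, since 9.89% of the neighbours within 50 bp fell too. In the other 7 libraries the share was 4.80% to 9.4%, so it does not set the 4 apart. Positions lower in 1 animal numbered 1421 to 2310 in each of the 4 and 967 to 1381 in each of the others. The share does not tell why the 4 held more. Positions higher in 1 animal numbered at least 3273 in each of the 4 libraries and at most 1768 in each other. A variant read as unmethylated in that animal alone does not explain them, since it would lower its level. A variant carried by all the other animals could leave 1 animal higher, and the counts cannot exclude this. Few independent DNA molecules stay open as an explanation. The correlation of deviations fell from 0.585 within 50 bp to 0.141 at 300 to 500 bp in animal 8, as short molecules would give. But it fell only from 0.714 to 0.401 in animal 6, a ratio of 0.562, the highest of the 4. Between positions at least 1000 bp apart the correlation was still 0.152 in animal 6, against 0.0271 to 0.0953 in every other library. Short molecules would not reach so far, so the scatter of animal 6 need not come from few molecules alone. In the other 7 libraries the correlation was 0.555 to 0.639 within 50 bp and 0.0935 to 0.269 at 300 to 500 bp. A fall with distance is therefore general and does not set the 4 apart. No biological explanation was tested, since the labels do not set these 4 animals apart.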

How the results depend on the processing

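The count of regions related to intake was 0 under each of 28 alternatives, and that of single CpGs was 0 under 23 of 24. The exception was intake as 2 classes, with 8 CpGs, and the cause was not tested. The 20 named regions kept the direction of their slope in 420 of 420 fits, of which the sign rule had fixed those without 1 animal and in cohort 14 alone, and passed in 0. The regions differing between cohorts numbered 0 to 2 without 1 animal. The calls came with 1 animal left in cohort 10, which the model assumes to vary like the others. For intake, leaving out either animal of cohort 10 equals cohort 14 alone, since the cohort term then fits the remaining animal exactly. A coverage minimum of 5 changes nothing, the lowest total being 12. Alternatives for promoters and gene lists were not run.

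The correlation of the overall mean level with intake was 0.334 from pooled reads and 0.444 to 0.668 without 1 animal, the highest without animal 6 of cohort 14, where the permutation p was 0.0333. Without the 4 libraries with most positions at the lowest unmethylated count, an alternative chosen after seeing the data, it was 0.909. For 20 to 39 CpGs within 250 bp it ran from 0.621, without animal 4 of cohort 14, to 0.778. Corrected for the level at unmethylated positions it was 0.585, and 0.603 with the added counts removed first. For 40 or more CpGs it was 0.522 to 0.7 without 1 animal, 0.652 in cohort 14 alone and 0.704 without the 4 libraries. Corrected, it was 0.524, 0.52 with the added counts removed first, and 0.542 from positions outside the dense classes alone. Its unadjusted permutation p of 0.0395 was not kept under 0.05 in these: p was 0.0523 to 0.118 without 7 of the 11 animals in turn, 0.0562 (exact) in cohort 14, 0.0833 (exact) without the 4 libraries, and 0.0869 to 0.103 corrected. The cause was not tested for these changes. No paired analysis was possible because the replicate numbers follow accession order and tie no animals together.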

Other observations

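The tests below were chosen after seeing the results they measure. Only the counts for the real intake values in the last paragraph come from planned fits. A small set of regions held an intermediate level in all 11 animals. Of 45982 regions with at least 20 CpGs, 239 lay between 40% and 60% in every animal with an SD under 3 points, and in 35 of these, on 18 chromosomes, at least 80% of the CpGs had a mean level between 30% and 70%. Among them, 65 CpGs on chromosome 10 from 93998084 to 93999070 had a mean level of 48.1% ± 2.41 (SD, n = 11). A region of 53 CpGs on chromosome 7 from 163045541 to 163046519 had 45.6% ± 2.26, and 1 of 54 CpGs on the same chromosome from 163043557 to 163044523 had 51.2% ± 1.75. On chromosome 14, 52 CpGs from 2074319 to 2075315 had 51.5% ± 2.47 and 50 CpGs from 2078332 to 2079310 had 48.5% ± 2.56. The pairs on chromosomes 7 and 14 lie close together, and regions were split at 1000 bp, so the 35 need not be separate loci.

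Other regions were methylated in 1 animal alone. A region of 68 CpGs on chromosome 1 from 171851051 to 171852040 was at 47.3% in animal 9 of cohort 14 and at 7.28% to 14.4% in the other 10. A region of 27 CpGs on chromosome 12 from 89498920 to 89499266 was at 33.9% in animal 8 of cohort 14, 1 of the 4 libraries whose levels scattered most, and 29 CpGs on chromosome 1 from 101703524 to 101703981 were at 31.4% in animal 1 of cohort 14. The CpGs that lay above every other animal by 10 points were 51 of 68, 15 of 27 and 14 of 29 in these 3 regions, so the last 2 were raised in part only.

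The longest lay on chromosome 4, where 3 adjacent regions with 336 CpGs from 55921540 to 55924526 were at 53.2%, 34.6% and 48.1% in animal 6 of cohort 14 and at most at 4.96%, 7.42% and 12.96% in the others. Single-position variants cannot give this, since 92.3% of the CpGs lay above every other animal by 10 points. Extra copies of the sequence would raise the depth. The depth ratios of the 3 regions to the median of the others, scaled to the library total, were 0.8355, 0.7508 and 0.982. Few molecules behind the reads stay open as an explanation. Of the windows of 200 bp, 15 of 15 lay above 15% and above every other animal, but this cannot decide. The regions had been picked for a level above 30% in animal 6 and under 15% in the others. Deviations in this library also stayed correlated at 0.401 at 300 to 500 bp, so few molecules need not let single windows fall back. Its levels scattered as 13.1 independent reads would, the fewest of all libraries. The windows ran from 21.3% to 61.7%, and no biological explanation was tested, nor a structural variant beside the island.

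Methylation at positions with 20 to 39 CpGs within 250 bp had a correlation of 0.703 with intake that did not pass after adjustment over 6 relations. Few molecules in the 4 libraries with most positions at the lowest unmethylated count do not account for it. In the 7 other animals r was 0.941 (exact permutation p = 0.00278, not adjusted over the 6 relations). Incomplete bisulfite conversion could account for part of it, and for part of the 0.941. The 7 animals were chosen after seeing the data, and no correction for conversion was run in them alone. Among the 7, the level at all nearly unmethylated positions was highest, 3.16%, in the animal of highest intake. It was 2.81% in the animal of lowest intake, and lowest, 2.45%, in animal 1 of cohort 10, with an intake value of 2.11. The level at 146198 nearly unmethylated positions outside the dense classes, with under 20 CpGs within 250 bp, ran with that of the class at r = 0.784. However, the level at those unmethylated positions had an r of 0.386 with intake (permutation p = 0.24). Correcting for that level took the slope from 0.222 ± 0.0738 to 0.127 ± 0.0541 points per unit of intake (permutation p of the correlation 0.0377), and correcting for all 985538 nearly unmethylated positions, of which 520801 are in the class itself, took it to 0.106 ± 0.0537 (permutation p 0.059, and 0.0492 with the added counts removed). With these levels as a covariate the slope was 0.156 ± 0.0496 and 0.142 ± 0.0499. At positions with 20 or more CpGs, slopes were 0.543 ± 0.297 at a pooled level of 20% to 40% and 0.586 ± 0.282 at 40% to 60%. The permutation p of their correlations was 0.0734 and 0.0717, and conversion alone would give slopes of 0.1145 and 0.0806. With under 20 CpGs the slopes were 0.0804 ± 0.264 and 0.0402 ± 0.347, against 0.1116 and 0.0786. The values for conversion are scaled from the slope of the level at all nearly unmethylated positions, 0.1555 ± 0.1186, and carry its error. They take that whole slope as conversion. The corrections fall on both sides of the threshold and the slopes by pooled level have wide errors. Conversion and a relation to intake therefore cannot be told apart here.

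With 0 regions and 0 single CpGs called for the real intake values, counting the arrangements of intake with as many calls decides nothing, since 100 of 100 for regions and 21 of 21 for CpGs follow from a count of 0. Of 99 reassignments, 2 called any region, and the highest count was 3. Of 20 reassignments, 1 called any single CpG, with a count of 2861. The number of CpGs at an unadjusted p under 0.05 was 55443 with the real values, and the lowest of the reassignments had 65739. It was 75396 without animal 9 of cohort 14 and 113754 with mean methylation as a covariate, models for which no reassignments were drawn.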
